A study of Trachinotus ovatus with 6 samples.

How the data were processed

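RNA from the gonads of 6 golden pompano (Trachinotus ovatus, a marine teleost fish) was sequenced: 3 ovaries and 3 testes, each from a different fish according to the study design. Total RNA was extracted with Trizol and made into Illumina libraries, per the labels' protocols. HISAT2 2.0.4 and StringTie 1.3.3b are named in the submitters' processing notes, which do not say in which order or with which settings they were run. The genome build, the source of the annotation and any filter on reads or genes are not given in the sources used here. The authors deposited 1 table of FPKM values (fragments per kilobase of gene model and per 1000000 fragments), with a column for each library, named by its sample title, and 22062 genes. Replicates were not pooled. The number of columns that belong to no sample was 0.

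FPKM is a relative unit, so a few very abundant transcripts lower the value of every other gene in the same library. The values were not whole multiples of a common step and no read totals were used, so absolute depth is unknown, no counting interval was computed and no count model was fitted. Relative depth was read from low values between 0.003 and 0.3 FPKM, where the ratio of a gene's values in 2 libraries clustered at ratios of whole numbers up to 4 (tolerance 0.003 on the log2 scale). The best-matching step put the depth of ovary 2 at 0.985 and that of ovary 3 at 1.024 of the depth of ovary 1. Genes with equal steps in ovary 1 and ovary 2 (69 genes, against 8 by chance at other offsets) had a median of 0.0123 FPKM in ovary 1, and those with equal steps in ovary 1 and ovary 3 (76 genes, against 10 by chance) had 0.0173 FPKM. Equal steps can stand for more than 1 read, so the worth of 1 read is not known. Between testes, and between ovaries and testes, no offset common to the pairs stood out, and the relative depth of the testes is unknown.

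Each gene is listed by an identifier and a position, which lies on a linkage group for all but 73 genes. The table pairs no identifier with a gene symbol or protein name. The 26 gene lists fixed before the data were examined, the Sox family among them, were therefore not tested, and no gene of the study's Sox family is reported here. For the same reason the rule for named genes could be followed in part only. It called for every Sox gene, the members of each list with the largest change, dmrt1, amh, gsdf, foxl2 and cyp19a1, the 5 genes with an informative name and the largest change in each direction among genes with a mean of at least 10 FPKM in the higher tissue and no overlap of replicates, and the 5 genes with the highest mean in each tissue. The last part was followed, with loci given by position. From the part on the largest changes, the condition of an informative name was dropped after the values were seen, and 2 identifiers in each direction are named. Positions are those of the deposited table. A gene's span runs from the start to the end of its locus, introns included, and spans of different genes can overlap.

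The main test was the moderated test of limma 3.58.1 (lmFit and eBayes with a mean-variance trend, two-sided) in R 4.3.3 on log2(FPKM + 1), for genes at 1 FPKM or more in at least 3 of the 6 libraries, with tissue as the only term and Benjamini-Hochberg adjustment. A gene past the threshold had an adjusted p under 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The main test, its filter and a set of alternatives were fixed before the data were examined. These alternatives were a pseudocount of 0.1, no filter, a filter on a mean of at least 5 FPKM, rescaling to TPM, scaling by median ratios, quantile normalization, fits without trend or with robust variances, the replicate number as a block, each library left out, an adjusted p under 0.01, and limma's treat against a log2 fold of 1. Titles number the fish 1 to 3 in both tissues, but ovaries and testes came from different fish and nothing else ties the numbers, so the main fit has no block.

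The following were chosen after the data were examined, with Python 3.11.15, scipy 1.17.1 and pandas 2.3.3. A gene was called testis-restricted when it reached 1 FPKM in each testis and stayed under 0.1 FPKM in each ovary, and ovary-restricted in the opposite case. For each of the 24 linkage groups and each direction, Fisher's exact test (two-sided) compared the share of tested genes past the threshold with a log2 fold of 1 or more with that on the other linkage groups, adjusted over 48 tests. The same shares were set against 10000 circular shifts of the calls along the genome, which keep neighbouring genes together. Adjacent tested genes whose spans do not overlap were compared with 10000 permuted gene orders. Genes are not independent replicates, and these tests describe these 6 libraries.

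The limma step was tested on simulated data: 17206 genes with the observed means and spreads, of which 200 were changed. It recovered 29.8% of genes changed by a log2 fold of 1 and 75.5% of those changed by 2. There were 0 calls in the wrong direction and 5 false calls. In the data most tested genes passed, so the adjustment was less strict there than in the simulation. These shares therefore do not measure recovery or error in the main comparison. The linkage group and neighbour steps were tested on simulated positions of calls as well. No pair of libraries held identical values.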

Results

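The gonads of golden pompano were profiled by RNA sequencing, with 3 ovaries from females and 3 testes from males, to compare gene expression between the sexes, with the Sox family, HMG-box transcription factors that include regulators of gonad development, as the subject named in the study's title. The table of FPKM values covers 22062 genes, of which 73 lie outside the 24 linkage groups and 271 are listed at 0 in all 6 libraries. Genes carry identifiers and positions but no names, so Sox genes are not reported and the results below describe genes by locus and in groups. The values of the 3 ovaries summed to 796856, 658899 and 733130 FPKM, and those of the 3 testes to 490967, 486141 and 485022 FPKM. Read depth is unknown.

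Libraries grouped by tissue. Over the 17206 tested genes, Pearson's r of log2(FPKM + 1) across genes was 0.961 to 0.99 between ovaries and 0.94 to 0.978 between testes, against 0.486 to 0.549 between an ovary and a testis. The first principal component held 93.6% of the variance and separated the tissues, while the second held 3.7% and ran mainly between ovary 1 (53.2) and ovary 2 (-41.7). Spread between libraries was somewhat larger in ovaries, with a median SD per gene of 0.24 on the log2(FPKM + 1) scale against 0.18 in testes. This spread includes library-wide offsets: log2 median ratios were -0.77, 0.16 and -0.1 in ovaries 1, 2 and 3, and 0.28, 0.17 and 0.28 in the testes. The pseudocount also lowers the SD of low genes.

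More genes reached 1 FPKM in testes than in ovaries, and the 100 most abundant genes took a larger share in ovaries. Genes at 1 FPKM or more numbered 17642 ± 316 in testes and 10094 ± 956 in ovaries (SD, n = 3 each). The median gene stood at 5.64 ± 0.478 FPKM in testes and at 0.711 ± 0.242 FPKM in ovaries (SD, n = 3 each). The 100 most abundant genes took 62.9% ± 8.22 of the summed FPKM in ovaries and 40.3% ± 1.16 in testes (SD, n = 3 each). The single most abundant gene went the other way, with 14.3% ± 1.27 in testes and 4.91% ± 1.32 in ovaries (SD, n = 3 each). In each of these 4 measures no ovary overlapped a testis. The exact two-sided permutation test gave p = 0.1 for each, the smallest value that 3 against 3 fish allow. Genes listed at 0 numbered 2745 ± 168 in ovaries and 451 ± 69.1 in testes (SD, n = 3 each). Many genes below 1 FPKM in ovaries were therefore above 0 there. Abundant genes lower all other values in this unit, so the counts at 1 FPKM depend on it. Ovaries also differed among themselves: 22 genes made up 50% of the summed FPKM in ovary 1, 69 in ovary 2 and 40 in ovary 3, against 262, 321 and 322 in the testes.

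**Figure D1:**
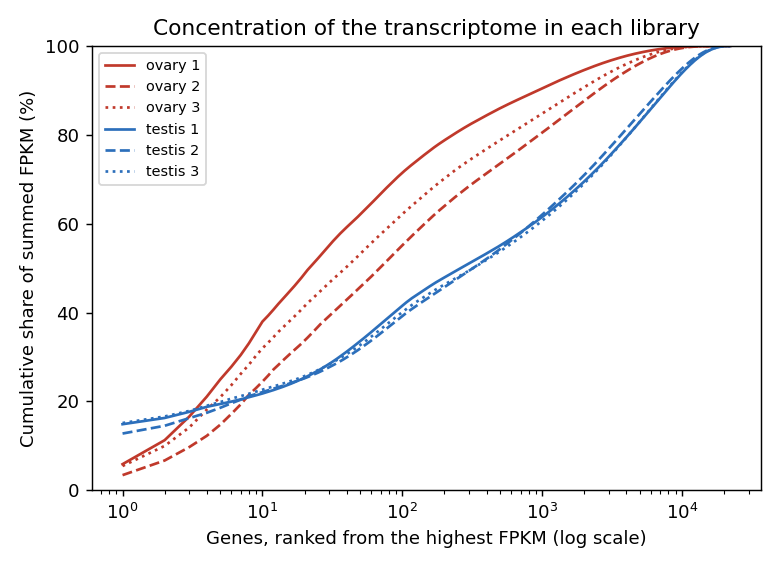
Cumulative share of the summed FPKM (vertical axis, percent) against genes ranked from the highest value (horizontal axis, log scale), with 1 line per library, ovaries in red and testes in blue. At the 100th gene the ovary lines lie at 71.5%, 55.1% and 62.2% and the testis lines at 41.5%, 39.2% and 40.1%.

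Most genes differed between the tissues, and most of those were higher in testis. Of the 17206 tested genes, 14035 (81.6%) passed an adjusted p of 0.05 in the limma test, 11729 of them higher in testis and 2306 higher in ovary. A log2 fold of 1 or more was reached by 10681 genes higher in testis and 1666 higher in ovary. By larger folds on this scale, 735 genes were higher in testis and 199 higher in ovary by a log2 fold of 4 or more, 83 and 74 by 6 or more, and 1 and 9 by 10 or more. These folds are limited for low genes by the pseudocount of 1: with 0.1 in its place, 4254 genes on linkage groups were higher in testis and 242 higher in ovary by a log2 fold of 4 or more. The remaining 3171 tested genes did not pass. The median log2 fold change of tested genes was 1.43 (testis over ovary), so the split between the directions depends on how libraries are put on one scale: testis-higher genes made up 83.6% of calls with FPKM as deposited, 90.1% with TPM (median 2.09), 76.9% with median ratio scaling (median 1.16) and 53.7% after quantile normalization (median 0.13). Relative to the median change of 1.43, a centring added after the data were examined that sets a near-even split by construction, 5857 genes were higher in testis and 5921 higher in ovary. Filtering on a mean of at least 5 FPKM gave 7562 genes past the threshold, of which 72.9% were higher in testis.

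**Figure D2:**
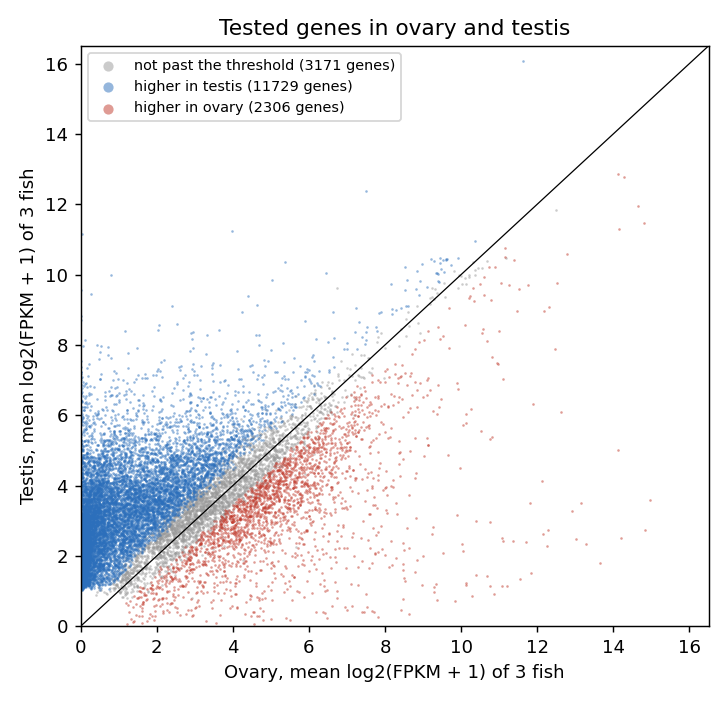
Mean log2(FPKM + 1) of the 3 testes (vertical axis) against that of the 3 ovaries (horizontal axis) for the 17206 tested genes, with the line of equal values. Blue points are the 11729 genes higher in testis, many of them close to 0 in ovary, red points the 2306 genes higher in ovary and grey points the 3171 genes that did not pass the limma test.

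By fixed limits on FPKM as deposited, many genes were expressed in testis and nearly absent from ovary, and few showed the opposite. These counts depend on the scale, on which the median gene stood at 5.64 FPKM in testes and 0.711 FPKM in ovaries. They were not repeated after quantile normalization. A gene abundant in ovary with a trace above the limit in any testis is not counted. The count of testis-restricted genes, at 1 FPKM or more in each testis and under 0.1 FPKM in each ovary, was 2159, and the count of ovary-restricted genes was 2. The testis-restricted genes were mostly of low abundance, with a median of 2.86 FPKM in testis, and together made up 3.73% of the summed FPKM there. Of them, 224 had a mean of at least 10 FPKM and the highest reached 2290 FPKM. In ovaries 125 of the 2159 were listed at 0 in all 3 libraries. The ovary-restricted genes lay on linkage group 8 (25215236 to 25219311), at 17.2, 32.2 and 20.7 FPKM in the ovaries, and on linkage group 21 (7095206 to 7095760), at 1.05, 1.72 and 1.26 FPKM. With a limit of 0.5 FPKM in the other tissue, 4818 and 40 genes were restricted to testis and ovary. By a ratio of means of at least 100, with 1 FPKM or more in every library of the higher tissue, 1566 genes were testis-biased and 86 ovary-biased. Leaving out a library can only keep or raise a count of restricted genes, though not the count by ratio of means. Ovary-restricted genes numbered 7 without testis 1 and 4 without ovary 1.

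The genes named here had the largest fold changes on the log2(FPKM + 1) scale. That scale favours abundant genes, so their abundance in one gonad is in part set by the choice. SCSFRI_TO_T_00041398, on linkage group 24 (13325614 to 13336120), had 2292 ± 177 FPKM in testis and 0.0343 ± 0.00592 FPKM in ovary (SD, n = 3 each), a log2 fold change of 11.11 (SE 0.18, limma adjusted p = 1.7e-07). Its ovary values lie under the pseudocount of 1, which limits this fold change, and a pseudocount of 0.1 gave 14.06. SCSFRI_TO_T_00048955, on linkage group 18 (18416900 to 18418350), had 763 ± 137 FPKM in testis (SD, n = 3) and was listed at 0 in all 3 ovaries (limma adjusted p = 4.4e-07). Its span overlaps those of 2 other genes. Among genes higher in ovary, SCSFRI_TO_T_00107380, on linkage group 10 (14906701 to 14908379), had 30563 ± 11273 FPKM in ovary (SD, n = 3) and 32.9, 0.237 and 6.22 FPKM in testes 1, 2 and 3. Its log2 fold change was -12.08 (SE 1.03, limma adjusted p = 1.1e-05), and it was -13.25 without testis 1 and -10.86 without testis 2. SCSFRI_TO_T_00014452, on linkage group 5 (16648185 to 16649640), had 13347 ± 4575 FPKM in ovary (SD, n = 3) and 12.2, 0.179 and 1.64 FPKM in the testes. Its log2 fold change was -11.86 (SE 0.78, limma adjusted p = 2.9e-06), -12.83 without testis 1 and -11.09 without testis 2. What these genes encode is not given in the table.

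The most abundant testis locus, on linkage group 6 (8497848 to 8675729), reached 69484 ± 6429 FPKM and held 14.3% ± 1.3 of the summed FPKM of each testis (SD, n = 3). It stood at 3305 ± 1151 FPKM in ovary, a log2 fold change of 4.45 (SE 0.22, limma adjusted p = 1.3e-06). A gene with nearly the same span (8497676 to 8675719) had 5368 ± 353 FPKM in testis and 185 ± 57 FPKM in ovary (SD, n = 3 each), a log2 fold change of 4.9. The span of each of these overlaps those of 11 genes, so reads could have been divided between overlapping models.

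The locus with the highest mean over the 3 ovaries lay on linkage group 20 (19012957 to 19028200), with 32885 ± 10301 FPKM (SD, n = 3), while the testes had 44.7, 2.52 and 9.71 FPKM. Its log2 fold change was -11.37 (SE 0.81, limma adjusted p = 4.1e-06), -12.34 without testis 1 and -10.49 without testis 2. SCSFRI_TO_T_00107380 was also among the 5 most abundant ovary genes. The other 3 were abundant in both gonads. A locus on linkage group 16 (14746782 to 14800512) had 46785, 9122 and 40010 FPKM in the ovaries, above the 43035 and 33181 FPKM of the linkage group 20 locus in ovaries 1 and 3 and below its 22439 FPKM in ovary 2, against 4165 ± 1585 FPKM in testis (SD, n = 3). The log2 fold change was -2.7 (limma adjusted p = 0.0031), and -3.45 without ovary 2. It did not pass after quantile normalization (-1.15, limma adjusted p = 0.26). A short locus on linkage group 9 (14839898 to 14840206) had 29281 ± 7069 FPKM in ovary and 2903 ± 903 FPKM in testis (SD, n = 3 each), a log2 fold change of -3.35, and of -1.05 after quantile normalization (limma adjusted p = 0.00054). A pair of overlapping loci on linkage group 13 was among the most abundant in testis as well. The locus from 17958283 to 18220829 had 20897 ± 8807 FPKM in ovary and 7119 ± 1239 FPKM in testis, and the locus from 18104176 to 18220858 had 18113 ± 4136 and 7484 ± 798 FPKM (SD, n = 3 each). Both were higher in ovary, with log2 fold changes of -1.49 and -1.26, but quantile normalization turned the direction of both. Their spans overlap those of 12 and 11 genes. The spans of the loci on linkage groups 20, 16 and 9 overlap those of 3, 2 and 4 genes. Reads could have been divided between overlapping models here too.

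**Figure D3:**
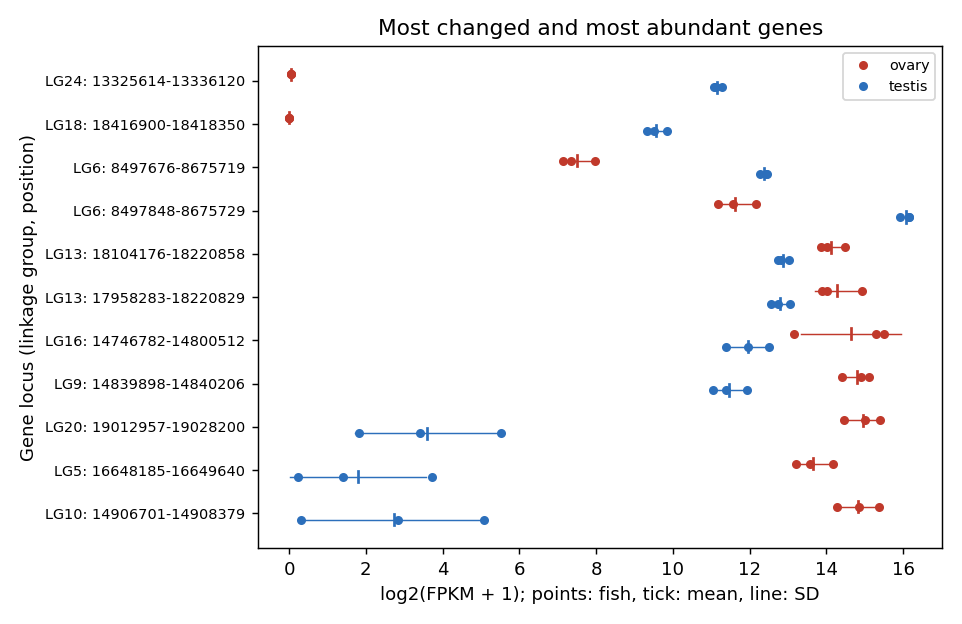
Log2(FPKM + 1) of the 11 loci described by position (horizontal axis), with 1 row per locus, points for single fish, a tick for the mean and a line for the SD (n = 3), ovaries in red and testes in blue. The 3 ovary-abundant loci on linkage groups 5, 10 and 20 show testis points far apart, while the testis-abundant loci on linkage groups 18 and 24 lie close to 0 in each ovary.

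Tissue-biased genes were found on every linkage group. The share of tested genes higher in testis by a log2 fold of 1 or more ran from 56.1% on linkage group 16 to 65.2% on linkage group 21, and the share higher in ovary from 7.6% on linkage group 21 to 12.3% on linkage group 20. Linkage group 16 had 370 testis-biased genes among 659 tested, against 62.3% on the other linkage groups, with Fisher's exact p = 0.0016 and p = 0.077 after adjustment over 48 tests. No linkage group passed in either direction, while 2 of 24 reached an unadjusted Fisher's exact p under 0.05 for testis and 1 of 24 for ovary. Linkage group 16 passed with median ratio scaling (adjusted p = 0.044 by Fisher's exact test) and without ovary 1 (adjusted p = 0.034 by Fisher's exact test). Permutation by circular shifts gave 3 unadjusted p under 0.05 in the 48 tests: 0.026 for linkage group 16 and 0.03 for linkage group 11, both for testis, and 0.013 for linkage group 20 for ovary.

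Genes whose identifiers begin with XLOC, 147 in the table, were mostly too low to test. Of the 28 tested, 19 were higher in testis and 6 higher in ovary in the limma test.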

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

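Alternatives not planned beforehand were centring on the median fold change, removal of the 100 highest genes of each library, and those for restricted genes and linkage groups. The main fit gave 14035 genes, 11729 higher in testis and 2306 higher in ovary, and with a log2 fold of 1 or more 10681 and 1666. A mean of at least 5 FPKM gave 7562 genes, 5509 higher in testis and 5027 of them by a log2 fold of 1, from the 10058 genes then tested. Quantile normalization gave 6867 higher in testis and 5919 in ovary, or 3966 and 3906 by a log2 fold of 1, and of the 10433 main calls that also passed there, 8957 had the same direction. Centring gave 5857 and 5921, or 3893 and 4681. Genes higher in ovary numbered 1410 with TPM, 1103 of them by a log2 fold of 1, and 1057 with treat. TPM multiplies the FPKM of all genes of a library by 1 factor, before the pseudocount is added. Centring lowers log2(FPKM + 1) of all genes in the testes by 1 amount, also for genes near 0. Quantile normalization moves genes by rank, and no value here decides which is right. The replicate block gave 13800 genes. Same-numbered ovaries and testes deviated with r = 0.009, -0.001 and -0.059 across genes, so no shared deviation by number was seen. Leaving out 1 library gave 13006 to 14578 genes past the threshold, 11026 to 12227 higher in testis, 1980 to 2964 higher in ovary, and 10032 to 11232 and 1572 to 1921 by a log2 fold of 1. Testis-restricted genes numbered 2159 in the main count, 1708 with median ratio scaling, 2541 with TPM and 4818 with a limit of 0.5 FPKM. Without 1 library they numbered 2228 to 2549, and leaving out a library can only keep or raise a count of restricted genes. Ovary-restricted genes numbered 2 to 7 without 1 library, 0 with TPM and 40 with that limit, against 2. Linkage groups past the threshold numbered 0 to 1 without 1 library and 1 with median ratio scaling, against 0. For the 11 loci, 193 of 198 alternative values kept direction and side of the threshold. The loci on linkage group 13 at 17958283 and 18104176 reversed to 0.79 and 0.85 after quantile normalization, and the cause was not tested. The 3 others no longer passed. Planned tests of Sox genes and of gene lists were not run, because identifiers carry no names. Unknown depth leaves counting error unmeasured for genes below 1 FPKM.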

Other observations

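All tests in this part were chosen after the results were seen.

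Strongly ovary-biased genes lay next to one another more often than a random gene order gives. Among 13055 adjacent pairs of tested genes with separate spans, 7 pairs were both higher in ovary by a log2 fold of 4 or more, against 1.74 in permuted orders (permutation p = 0.0026, 10000 orders). These pairs lay on linkage groups 3, 6, 9, 12, 13, 22 and 24. The pair with the largest changes was on linkage group 13 (14575238 to 14588894), with log2 fold changes of -9.13 and -7.44, followed by a pair on linkage group 12 (23903922 to 23912827) with -7.24 and -5.93. Strongly testis-biased neighbours numbered 37 pairs against 23.97 (permutation p = 0.006). Over all pairs the log2 fold changes of neighbours correlated with r = 0.058 across genes, above the 95th percentile of permuted orders of 0.015 (p = 0.0001, the smallest that 10000 permutations can give), and r was 0.058 to 0.064 with TPM, median ratio scaling, quantile normalization and a pseudocount of 0.1. Neighbours may share tissue bias because of tandem copies or shared regulation. Sequence similarity was not examined, so reads shared between tandem copies also stay open.

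The median log2 fold change (testis over ovary) was 0.94 in the fifth of genes with spans up to 5001 bp and 1.76 in the fifth with spans of 28868 bp or more, with Spearman's rho of 0.19 across genes. After quantile normalization the medians were -0.05 and 0.25 and rho was 0.09.

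Most genes past the threshold were higher in testis, and 3 technical explanations were examined as the whole cause. The table argues against 1 of them, too few ovary reads to detect genes. With the 100 highest genes of each library removed (174 genes) and the rest rescaled to equal sums, the median log2 fold change was 1.3 (1.22 to 1.36 with any 1 library left out) and 80.1% of calls were higher in testis. The same rescaling with no gene removed gave 1.79 and 90.1%. The 174 removed genes therefore account for part of the shift on that scale and not for all of it. Sums of the remaining genes still set that scale, so the test cannot exclude an effect of the next most abundant genes. The median was 1.16 with median ratio scaling and 0.13 after quantile normalization, which moves genes by rank. Of the genes higher in testis, 98.9% had a value above 0 in at least 1 ovary, as did 94.2% of the testis-restricted genes, so the ovary libraries resolved levels well below those in testis. Genomic DNA in the testis libraries at an even level over genes, as the whole cause, would hold all genes at or above that level. Subtraction of the 10th percentile of each testis library (0.37, 0.258 and 0.323 FPKM) left a median of 1.33 (1.2 to 1.44 with any 1 library left out) and 82.7% of calls higher in testis, and subtraction of the 20th percentile left 1.1 (0.95 to 1.22) and 80.2%. On the log2(FPKM + 1) scale, subtraction of such low levels can lower a gene only by a limited amount. It could not have removed the shift, so these medians cannot decide on DNA as the whole cause. They show only that even levels no higher than these leave most of the shift on this scale. Genomic DNA in the testis libraries, a broader testis transcriptome and a different amount of RNA per cell in the gonads stay open, and the last 2 were not tested. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes as the real one in total, higher in testis and higher in ovary, namely the real one (14035 genes, against at most 0 in the others), and 10 splits are too few for a share under 0.05.

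Some transcripts abundant in 1 gonad appeared in the other at a low level, in both directions. Over the 490 genes with at least 100 FPKM in each ovary, the 5th percentile of the share of the mean ovary level was 0.281% in testis 1, 0.0562% in testis 2 and 0.0945% in testis 3, and the lowest share was 0.0358%, 0.000697% and 0.0123%. The median shares were 26.5%, 28.5% and 27.4%, so testis 1 stood highest only among the low shares. Over the 323 genes with at least 100 FPKM in each testis, the 5th percentile of the share of the mean testis level was 0.165% in ovary 1, 0.433% in ovary 2 and 0.346% in ovary 3, with a lowest share of 0 in each. Over 32 of the 490 ovary-abundant genes, chosen for a share under 0.1% in testis 2, testis 1 exceeded testis 3 in 32, while testis 2 is low by the choice. Over the same 32 genes the log2 level rose with the log2 ovary level with a slope of 0.9 in testis 1 and 0.809 in testis 3, but the choice of genes alone gives such slopes: 2000 permutations of the shares over the ovary levels, with the same choice, gave 0.86 to 1.14 and 0.78 to 1.21 (95% ranges). Traces of ovary material in the testis libraries, in 1 proportion per library, and low expression in the testis itself therefore both stay open. Exchange of reads between pooled libraries stays open too: 6 of 323 testis-abundant genes lay in all 3 ovaries below 0.0358%, the lowest share of any ovary-abundant gene in testis 1, but only 2 of the 6 had a value above 0 in every ovary. SCSFRI_TO_T_00041398, at 2292 FPKM in testis, is one of these, with 0.0372, 0.0382 and 0.0275 FPKM in the ovaries.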
